A study of Mus musculus with 4 samples.

How the data were processed

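Bulk RNA sequencing was done on ILC2s sorted from the colon of 4 C57BL/6J mice, 2 on a control diet and 2 on a high-fiber diet, with each sample from 1 mouse per the series' design text. Per the labels' protocols, libraries were made from total RNA of the sorted cells with a SMARTer ultra-low-input kit, which copies polyadenylated RNA and amplifies it by PCR. The labels give neither the gates of the sort, the cell numbers, the kind of fiber nor the time on the diet. CASAVA 1.8.2, STAR 2.3.0 and the mm10 genome build are named in the submitters' processing notes, without their roles. The counting program and its settings, including strand, are not given in the sources used here, so reads of overlapping or antisense genes and of near-identical copies may be split or shared.

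The deposited table holds whole-number read counts per gene and library, not normalized, for 27179 NCBI gene identifiers, and 0 of its value columns lacked a sample. Identifiers were matched to symbols through the RefSeq annotation of GRCm38.p6, whose primary chromosomes are those of mm10. A symbol was found for 25275 identifiers. The other 1904 stayed in the test under their number and held 0.212% to 0.248% of the counts of a library. Totals per library were 20253987 to 30406730 counts. In both diets the library numbered 1 was the deeper one. At these depths a gene at 0 counts may hold up to 3 counts, and intervals and floors cover counting error only, since PCR copies are not independent molecules.

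The deposited counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, which left 11841 of the 15425 with any count, and libraries were scaled by TMM. The model held an intercept and the diet, with positive log2 fold changes meaning higher on the high-fiber diet. Dispersions were estimated with estimateDisp, and glmQLFit was run with legacy=FALSE and robust off, followed by glmQLFTest and Benjamini-Hochberg adjustment at 0.05. The written design named the test but not the legacy setting. The older fit (legacy=TRUE) was listed beforehand as an alternative, yet it is the default of edgeR 4.0.16. An exploratory fit with that default was seen before the fit reported here, and it called 0 genes. The common biological coefficient of variation was 0.607, with 2 residual degrees of freedom. Standard errors of log2 fold changes were taken from the fold change and the F statistic. Values in CPM were computed from the counts and TMM-scaled library sizes and are given as mean ± SD over 2 mice. A fold against a group with 0 counts was set against 3 counts over that group, and ratios of few counts carry an exact 95% binomial interval. Such a fold pools both libraries of the other group and leaves out the spread between mice.

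In advance, 33 gene lists were fixed, on cell functions, on RNA quality and on markers of other cell types that the gate could hold. They were tested with camera at a preset correlation of 0.01 where at least 5 members were tested (28 lists), with an estimated correlation and fry beside it. Members were counted at an adjusted p under 0.05 over all genes and adjusted over the list alone. Il10, Socs3 and some other genes stand in more than 1 list. The sorted ILC2s themselves express some markers of other cell types. A gene of the ILC3 list counts in the list tests but is not reported here by itself.

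Named genes followed a rule: genes past the threshold with groups that do not overlap and a mean of at least 5 CPM, up to 10 per direction by fold; up to 4 called members per list; a panel of 12 ILC2 genes and the sex-linked genes; where fewer than 5 genes passed, the 10 of smallest p in that direction at a mean of 5 CPM or more; and the 3 most abundant members of other cell type lists that passed camera. Other list members given as examples were chosen after their values were seen. The samples, the lists, the tests of genes and lists except the legacy setting, this rule and the alternatives other than those said to be added later were set before the data were examined. The tests of marker gains, library order, kappa V genes, the heat shock median and library splits were chosen after the results were seen.

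Alternatives were RLE, upper-quartile and no scaling factors, no filter on low counts, a filter of 5 CPM in at least 2 libraries, DESeq2 1.42.0, limma-voom (limma 3.58.1), legacy=TRUE, robust fitting, a replicate block, each library left out in turn, ribosomal, mitochondrial and hemoglobin genes left out, and an adjusted p of 0.1. DESeq2 without each library, with a block, and on the genes kept by filterByExpr was added after seeing the data. The tests were checked on simulated data for this comparison, drawn from the means, depths and gene-wise dispersions of the 11841 genes in these same libraries. Over 10 simulations together 500 genes were changed at each fold, so the shares below may not carry over where fewer genes change. Over 10 simulations edgeR recovered 3% of genes changed 2-fold, 38% at 4-fold, 54.2% at 8-fold and 70.4% at 32-fold, with 4.5 unchanged genes called per simulation. DESeq2 recovered 12.6%, 54.2%, 69.8% and 82.8%, with 80.8 unchanged genes called per simulation. With no gene changed, camera called 1 list in 10 simulations. Each gene was drawn independently, so this cannot show how often camera calls lists whose members vary together. Figures were drawn with matplotlib 3.10.9.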

Results

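Group 2 innate lymphoid cells (ILC2s) are tissue lymphocytes that lack antigen receptors and release type 2 cytokines such as IL-5 and IL-13. RNA was sequenced from ILC2s sorted from the colon of C57BL/6J mice fed a control diet or a high-fiber diet. Each library came from 1 mouse, with 2 mice per diet. Library totals were 30406730 and 20253987 counts on the control diet and 29263068 and 20750263 counts on the high-fiber diet. A count was present for 12685 to 13399 genes per library, and 11841 genes entered the test. Across genes, which are not independent replicates, Spearman correlations between libraries lay between 0.916 and 0.951. Each counted as its own sample, since each came from its own mouse. The chi-square per gene between libraries was 83.6 or more, but PCR copies raise this value, so it cannot by itself tell separate samples from repeats. Of the variance between libraries, 45.8% lay on a first principal component that set high-fiber library 2 (116) apart from high-fiber library 1 (-10.0) and from both control libraries (-59.3 and -46.7).

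The comparison asked which transcripts of colonic ILC2s differ between mice on the high-fiber and the control diet. Transcripts of Ctla4, an inhibitory receptor of activated lymphocytes, and of Il17a, the cytokine of type 3 immunity, rose on the high-fiber diet, as did Tnfsf8, which encodes the CD30 ligand. In counts scaled to equal library size (CPM), Ctla4 went from 0.066 ± 0.094 on the control diet to 122 ± 11 on the high-fiber diet (SD, n = 2 each). The control libraries held 4 Ctla4 counts together and the high-fiber libraries 6085, a ratio of 1581 with a 95% counting interval of 617 to 5805. Il17a went from 1.37 ± 0.29 to 85.8 ± 13.2 CPM, a log2 fold change of 6.00 ± 0.48 (SE). Tnfsf8 went from 9.47 ± 0.52 to 280 ± 101 CPM (4.88 ± 0.39). The fourth gene to rise was Hmga2-ps1, a transcribed pseudogene, at 3.53 ± 0.32. Its reads may be shared with its parent gene Hmga2, so its value is uncertain.

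These 4 genes were higher in both high-fiber libraries than in either control library, and 0 genes were lower, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 11841 genes. Adjusted p was 0.0306 for Ctla4, Il17a and Tnfsf8 and 0.0484 for Hmga2-ps1. At an unadjusted p under 0.05, 557 genes were higher and 485 lower, 1042 in all. A uniform p would give 592.05, and simulations with no changed gene gave a mean of 702. Each gene was simulated independently, so the simulations cannot show how far such counts move when genes vary together. DESeq2 called 158 genes higher and 78 lower, and limma-voom called 0. In simulations with no changed gene DESeq2 called a mean of 46.8 genes, and edgeR called 2 genes in 10 simulations together. Groups did not overlap for 38.2% of tested genes, where chance gives 33.3%. With edgeR's older quasi-likelihood fit, which is the default of the release used here, 0 genes passed (smallest adjusted p = 0.0813, with 461 higher and 377 lower at an unadjusted p under 0.05). Leaving out control library 1, control library 2, high-fiber library 1 or high-fiber library 2 also ended each of the 4 calls with edgeR, with smallest adjusted p over all genes of 0.110, 0.346, 0.0327 and 0.10, while DESeq2 kept the 4 genes each time.

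In the GRCm38 assembly Ctla4 (NCBI gene 12477) lies on chromosome 1 from 60909025 to 60915832. Il17a (NCBI gene 16171) lies on chromosome 1 from 20730905 to 20734496, and its neighbour Il17f (NCBI gene 257630) from 20777146 to 20785274. Tnfsf8 (NCBI gene 21949) lies on chromosome 4 from 63831202 to 63861508.

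Next by p, above the threshold, came Lgmn, Il17f, Pcsk1, Penk, Cst7 and the long noncoding RNA Gm14718. Lgmn, the lysosomal protease legumain, was at 41.9 ± 9.80 CPM on the control and 344 ± 66.3 CPM on the high-fiber diet (3.02 ± 0.29, adjusted p = 0.0585). Il17f was at 11.2 ± 5.61 and 395 ± 212 CPM (5.09 ± 0.54, adjusted p = 0.0931). Pcsk1, a prohormone convertase, was at 34.2 ± 4.79 and 172 ± 6.32 CPM (2.32 ± 0.26, adjusted p = 0.104). Penk, which encodes proenkephalin, was at 12.1 ± 10.9 and 262 ± 71.7 CPM (4.35 ± 0.55, adjusted p = 0.195). Log2 fold changes were 2.00 for Cst7, an inhibitor of cysteine proteases, and 3.71 for Gm14718. DESeq2 called all 6 higher, with adjusted p between 6.32e-08 for Cst7 and 8.69e-25 for Il17f.

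**Figure D1:**
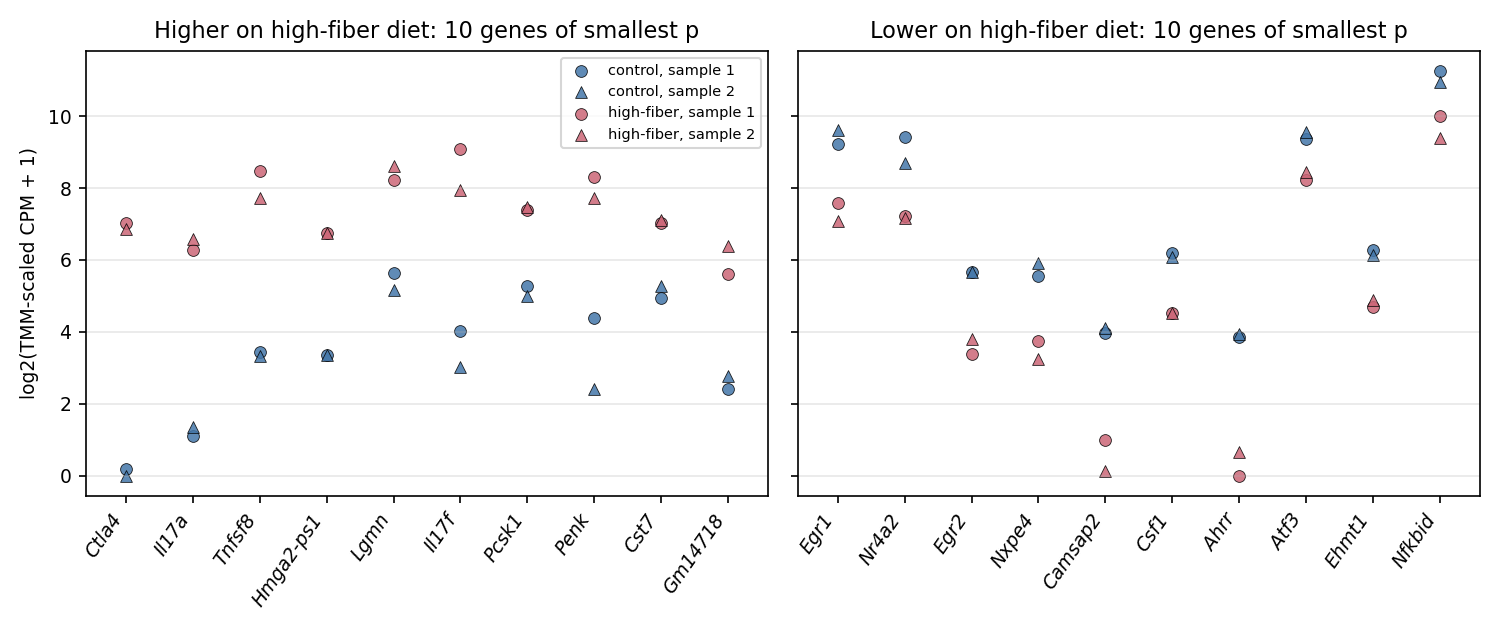
Expression of the 10 genes of smallest p in each direction, as log2 of TMM-scaled CPM plus 1 on the vertical axis, with 1 point per mouse. Blue points are control and red points are high-fiber mice, circles are libraries numbered 1 and triangles those numbered 2. The red and blue points do not overlap for any of these genes, which were chosen by p. Only Ctla4, Il17a, Tnfsf8 and Hmga2-ps1 passed the adjusted threshold in edgeR.

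No gene passed in the downward direction with edgeR, where 485 genes lay at an unadjusted p under 0.05 and DESeq2 called 78. The smallest p belonged to Egr1, an immediate early transcription factor induced by receptor signalling, at 693 ± 133 CPM on the control and 162 ± 39.3 CPM on the high-fiber diet (-2.10 ± 0.27, adjusted p = 0.212). Nr4a2 (-1.93), Egr2 (-2.18) and Atf3 (-1.13), further genes of the same response, followed with Nfkbid (-1.37), an inhibitor of the NF-kB family. Csf1, the macrophage growth factor, was at 69.2 ± 4.06 and 21.8 ± 0.023 CPM (-1.67 ± 0.30, adjusted p = 0.358). Ahrr, the repressor of the aryl hydrocarbon receptor, had 710 counts in the control libraries and 12 in the high-fiber libraries (-5.80 ± 1.15, adjusted p = 0.358). Nxpe4 (-2.29), Camsap2 (-4.60) and the histone methyltransferase gene Ehmt1 (-1.46) completed the 10. With a filter of 5 CPM in at least 2 libraries, Egr1 passed as the 1 lower gene.

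Genes that define ILC2s did not singly pass edgeR's test in either direction. As a list they did pass fry's test for change in either direction (adjusted p = 0.0362). Of 27 tested genes in the ILC2 identity list, 0 passed by edgeR over all genes and 0 adjusted over the list alone (camera adjusted p = 0.477), while 3 were higher and 2 lower at an unadjusted p under 0.05. DESeq2 called 1, Kit, higher (243 ± 42.5 and 523 ± 203 CPM, DESeq2 adjusted p = 0.0409). Gata3, the lineage transcription factor, was at 1320 ± 417 and 1031 ± 375 CPM (-0.36 ± 0.34). Log2 fold changes were 0.22 for the IL-33 receptor gene Il1rl1, 0.23 for Il7r, -0.18 for Klrg1, 0.015 for Rora, 0.22 for Arg1 and 0.0012 for the IL-25 receptor gene Il17rb. The signs of Rora and Il17rb turned without scaling factors. Il5 was at 2801 ± 342 CPM on the control and 4844 ± 1478 CPM on the high-fiber diet (0.79 ± 0.28, adjusted p = 0.496). Il13 (0.19), Areg (0.12) and Il4 (-0.48) had adjusted p of 0.957, 0.941 and 0.613. Of 24 tested type 2 and effector cytokine genes 0 passed by edgeR over all genes, and Penk alone did when adjusted over the list alone (camera adjusted p = 0.396). DESeq2 called 2 of them higher, Penk and Calca. Mki67, a marker of dividing cells, held 4, 46, 5 and 317 counts in control libraries 1 and 2 and high-fiber libraries 1 and 2, and its log2 fold change of 2.80 became -2.48 without high-fiber library 2. Of the 5 sex-linked genes, the Y-linked Ddx3y (-0.24), Uty (-0.28), Eif2s3y (0.081) and Kdm5d (-0.37) had counts in every library and Xist did not enter the test.

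Inhibitory and checkpoint genes ranked higher on the high-fiber diet as a list (camera adjusted p = 7.61e-04), with adjusted p = 0.776 with an estimated correlation. Benjamini-Hochberg adjustment gave many lists this same value. Among the called lists sharing it, unadjusted camera p with an estimated correlation ran from 0.0616 for this list to 0.333 for cholesterol biosynthesis. Of 21 tested members, Ctla4 rose over all genes, and 3 rose adjusted over the list alone: Ctla4, Tox2 and Tigit. Tigit, an inhibitory receptor, was at 7.56 ± 7.19 and 56.9 ± 0.15 CPM (2.80 ± 0.56), and Tox2, a transcription factor, at 1.11 ± 1.53 and 34.1 ± 29.4 CPM (5.24 ± 1.19). Pdcd1, which encodes PD-1, was at 357 ± 85.5 and 945 ± 501 CPM (1.40 ± 0.40). DESeq2 called these 4 higher. The list median was 0.084 and its mean 0.98, so a few members carried the call. It did not pass without control library 2 (adjusted p = 0.0606), without high-fiber library 1 (0.257) or with limma-voom (0.372).

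The ILC3 marker list, fixed as markers of another innate lymphoid cell type, ranked higher by camera (adjusted p = 0.0484, and 0.776 as the adjusted p with an estimated correlation), although its median was -0.30 against a mean of 0.46. Of 10 tested members Il17a rose over all genes, and Il17a and Il17f rose adjusted over the list alone. The other 8 had negative log2 fold changes. Tmem176b (-0.059), Tmem176a (-0.18) and Tnfsf11 (-0.42) were the most abundant members, and the 2 Tmem176 genes overlap, so reads could be split between them. Il22, Il23r and Ccr6 had 0 counts in all 4 libraries, and each 0 allows up to 3 counts per library. The list call did not pass in any of the 4 fits without 1 library (adjusted p from 0.111 to 0.407) or with RLE scaling (0.0526), and with limma-voom the direction turned (0.772). T cell markers, from cells that also make Ctla4 and Il17a, ranked lower without passing (camera adjusted p = 0.625, 0 of 15 tested members passing by edgeR). DESeq2 called 1 member, Themis, lower (14.0 and 1.96 CPM, DESeq2 adjusted p = 0.00976). Cd3g, at 157 ± 19.8 and 267 ± 31.6 CPM, was higher at an unadjusted p of 0.0132 and passed with neither edgeR nor DESeq2. Cd3e was at 9.50 and 3.26 CPM, Cd3d at 3.87 and 2.97 CPM and Trac at 12.3 and 7.38 CPM on the control and high-fiber diets. Foxp3 was at 0.090 and 2.18 CPM, with 4.22 CPM in high-fiber library 2.

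**Figure D2:**
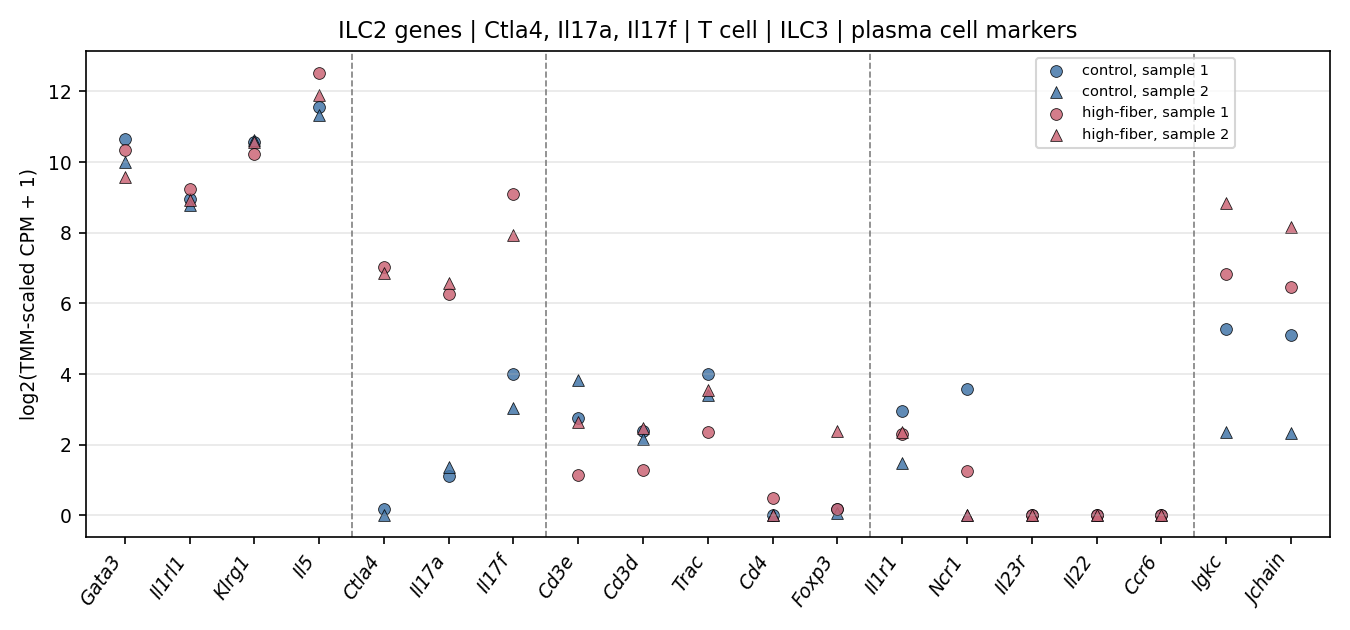
Expression of ILC2 genes, of Ctla4, Il17a and Il17f, and of T cell, ILC3 and plasma cell markers, as log2 of TMM-scaled CPM plus 1 on the vertical axis, with 1 point per mouse. Colours and symbols mark the diet and the library number as given in the legend, and dashed lines separate the groups of genes. Ctla4 reached 122 CPM and Il17a 85.8 CPM on the high-fiber diet, while Cd3e stood at 3.26 CPM and Il22, Il23r and Ccr6 at 0.

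B and plasma cell markers ranked higher on the high-fiber diet (camera adjusted p = 8.29e-06, and 0.776 as the adjusted p with an estimated correlation). Of 8 tested members 0 passed by edgeR over all genes, 5 rose adjusted over the list alone, and DESeq2 called 0. The median log2 fold change was 3.08, unchanged with Iglc2, at 0 counts on the control diet, set to its bound. Igkc, the kappa light chain constant region, was at 37.4 and 4.15 CPM in control libraries 1 and 2 and at 112 and 458 CPM in high-fiber libraries 1 and 2. Igha (60.4, 3.29, 101 and 424 CPM) and Jchain (33.4, 4.05, 88.0 and 286 CPM) put the libraries in the same order. Ighm, the mu heavy chain, was at 549 ± 94.6 and 483 ± 91.7 CPM (-0.18 ± 0.24). The call passed in each of the 4 fits without 1 library.

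Beside these markers, the lists of MHC class II presentation, of macrophages, monocytes and dendritic cells, and of endoplasmic reticulum stress and secretion ranked higher. With an estimated correlation each of the 3 had an adjusted p = 0.776, and 0 members of any of them passed by edgeR over all genes or adjusted over the list alone. DESeq2 called 1 member, H2-Ab1, higher (DESeq2 adjusted p = 0.0313). For MHC class II (camera adjusted p = 0.00413, 9 of 11 tested members positive), H2-Ab1 was at 122 ± 23.5 and 249 ± 49.4 CPM (1.04 ± 0.26) and the invariant chain gene Cd74 at 544 ± 52.5 and 908 ± 270 CPM (0.74 ± 0.26). This call passed in each fit without 1 library. For the macrophage, monocyte and dendritic cell list (camera adjusted p = 0.0484, 13 of 17 positive), Apoe was at 120 ± 48.6 and 197 ± 7.16 CPM, the lysozyme gene Lyz2 at 48.8 ± 37.5 and 88.9 ± 23.5 CPM, and Zbtb46 at 84.6 ± 14.7 and 65.9 ± 5.43 CPM. It was lost without control library 1 (0.559), high-fiber library 1 (0.118) or high-fiber library 2 (0.224), and with RLE (0.0526) or upper-quartile (0.0548) scaling. For endoplasmic reticulum stress (camera adjusted p = 0.00285, 19 of 24 positive), Manf (0.74 ± 0.22) and Sdf2l1 (0.74 ± 0.25), both induced by unfolded proteins, had the smallest p. This call was lost without control library 2 (0.232) or high-fiber library 1 (0.0516).

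Nuclear genes of oxidative phosphorylation ranked higher on the high-fiber diet (camera adjusted p = 7.61e-04), with adjusted p = 0.776 with an estimated correlation. Of 44 tested members 37 had positive and 7 negative log2 fold changes, with a median of 0.32. None passed over all genes or adjusted over the list alone by edgeR, 2 lay at an unadjusted p under 0.05, and DESeq2 called 0. Sdhb, a subunit of succinate dehydrogenase, was at 221 ± 12.1 and 346 ± 78.7 CPM (0.64 ± 0.24), and Uqcrq, a subunit of complex III, at 151 ± 4.06 and 232 ± 48.5 CPM (0.61 ± 0.24). The mitochondrially encoded transcripts did not pass (median 0.14, camera adjusted p = 0.742). The oxidative phosphorylation call was lost without control library 1 (0.111) or high-fiber library 2 (0.0888).

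Immediate early and AP-1 genes, which lymphocytes switch on within minutes of stimulation and which cell isolation also induces, ranked lower on the high-fiber diet (camera adjusted p = 1.04e-12). With an estimated correlation the adjusted p was 0.776, the value shared by many lists, and the unadjusted camera p was 0.0707. Of 35 tested members 31 had negative log2 fold changes, with a median of -0.46. None passed over all genes by edgeR, 13 were lower at an unadjusted p under 0.05, 6 fell adjusted over the list alone (Egr1, Nr4a2, Egr2, Atf3, Fos and Nr4a1), and DESeq2 called 8 lower. Fos was at 6214 ± 270 CPM on the control and 2788 ± 517 CPM on the high-fiber diet (-1.16 ± 0.24), and Nr4a1 at 5233 ± 1264 and 1696 ± 982 CPM (-1.62 ± 0.43). The list passed in each fit without 1 library. Heat shock and chaperone genes also ranked lower (camera adjusted p = 0.0484, and 0.833 as the adjusted p with an estimated correlation), with 13 of 16 tested members negative and 0 passing by edgeR over all genes or adjusted over the list alone. DESeq2 called 1 member, Dnajb4, lower (DESeq2 adjusted p = 0.0351). Control library 2 carried this call: Dnajb1 stood at 838 and 3406 CPM in control libraries 1 and 2 and at 1105 and 983 CPM in high-fiber libraries 1 and 2. Without control library 2 the list pointed upward (adjusted p = 0.342), and without high-fiber library 1 it did not pass (0.371). Nor did it pass with RLE (0.0526) or upper-quartile (0.0548) scaling or with limma-voom (0.179).

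Cholesterol biosynthesis genes ranked lower on the high-fiber diet (camera adjusted p = 0.0206), with adjusted p = 0.776 with an estimated correlation. Of 23 tested members 16 had negative log2 fold changes, the median was -0.37, and 0 passed over all genes or adjusted over the list alone by edgeR, while 3 were lower at an unadjusted p under 0.05 and DESeq2 called 0. Dhcr7, the last enzyme of the pathway, was at 29.8 ± 2.68 and 11.2 ± 0.00061 CPM (-1.41 ± 0.41), and Mvd at 38.6 ± 2.78 and 19.6 ± 5.41 CPM (-0.95 ± 0.37). The list did not pass without control library 1 (0.372) or without high-fiber library 2 (0.137).

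**Figure D3:**
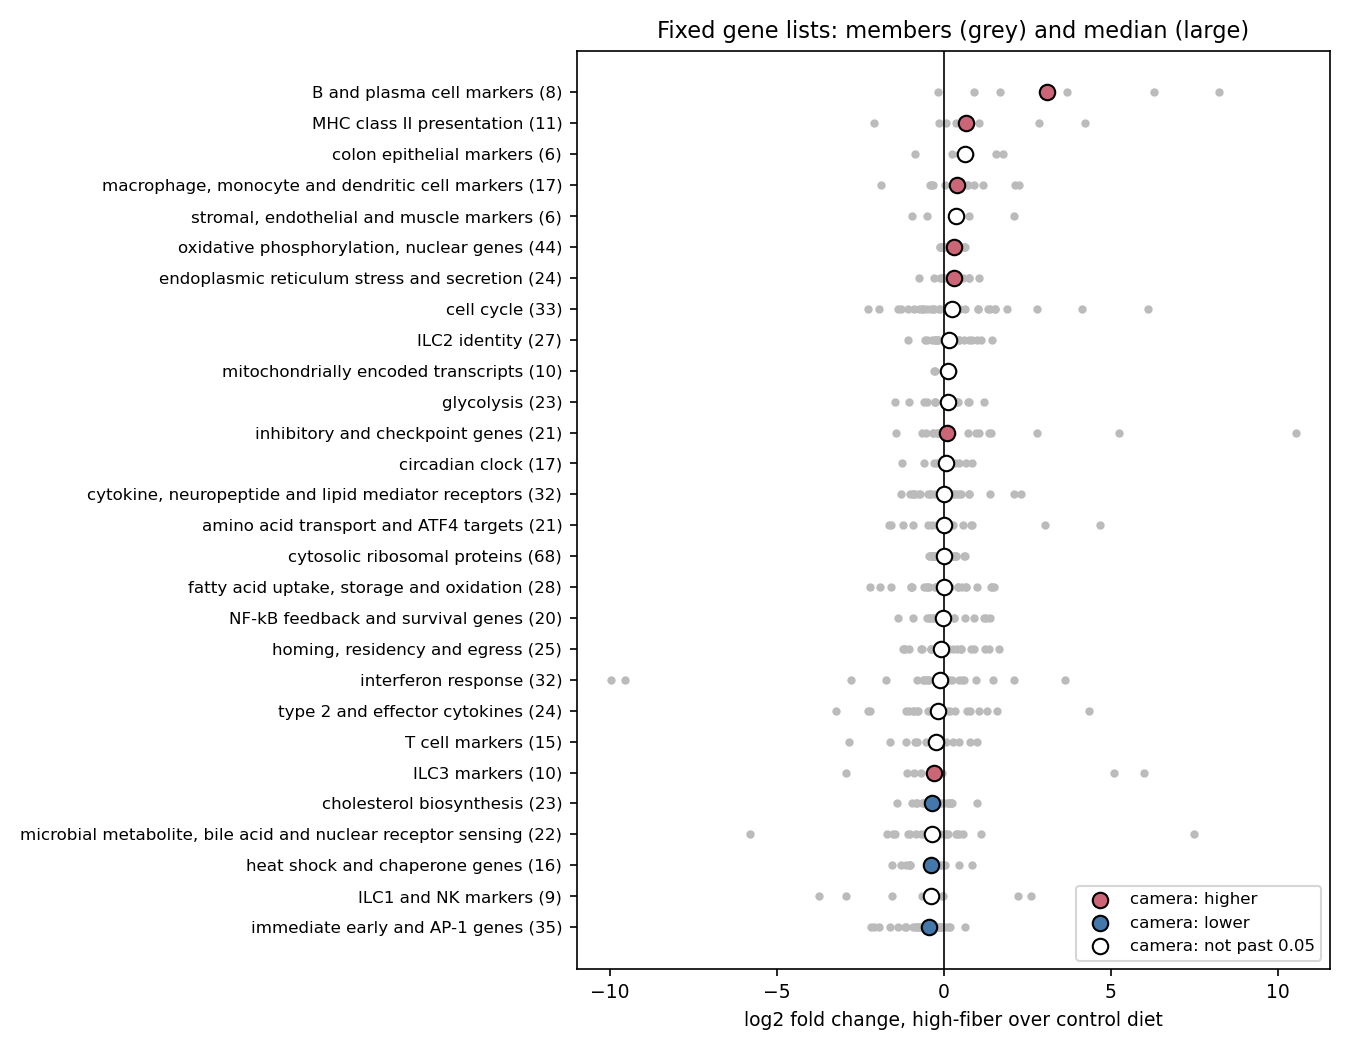
Log2 fold changes, high-fiber over control diet, of the tested members of the 28 fixed lists with at least 5 tested members. Grey points are genes, large points are list medians, and the number of tested members stands in brackets. Red medians mark the 7 lists camera called higher and blue medians the 3 it called lower, at a preset correlation of 0.01. With an estimated correlation 0 lists passed.

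Of the 28 lists tested, 18 did not pass camera. Among genes of microbial metabolite, bile acid and nuclear receptor sensing (22 tested, median -0.37, camera adjusted p = 0.145), only Ahrr fell adjusted over the list alone. At an unadjusted p under 0.05, 1 member was higher and 2 were lower. The short-chain fatty acid receptor gene Ffar2, an example chosen after its value was seen, passed with neither edgeR nor DESeq2. It was at 27.6 ± 6.27 and 13.5 ± 4.02 CPM (-1.01 ± 0.45). In the list of NF-kB feedback and survival genes (20 tested, adjusted p = 0.961), Tnfrsf9 (1.37 ± 0.29) and Cd83 (1.20 ± 0.29) rose and Nfkbid fell adjusted over the list alone. Of amino acid transport and ATF4 target genes (21 tested, adjusted p = 0.477), Cebpb (3.03 ± 0.61) and Asns (4.68 ± 1.09) rose adjusted over the list alone. In the interferon response list (32 tested, camera adjusted p = 0.477), Cmpk2 and Ifit2 had 0 counts on the high-fiber diet. Against both control libraries pooled, they were at least 78.2-fold and 60.6-fold lower on that diet, with 3 counts set over the group. DESeq2 called both, and control library 2 held 219 of the Cmpk2 counts against 25 in control library 1. By edgeR no member passed over all genes or adjusted over the list alone in the lists of cytokine, neuropeptide and lipid mediator receptors (camera adjusted p = 0.957), cell cycle (0.957), homing, residency and egress (0.752), glycolysis (0.477), fatty acid uptake, storage and oxidation (0.876) and circadian clock (0.546). The same held for cytosolic ribosomal proteins (0.957), ILC1 and NK markers (0.372), colon epithelial markers (0.255) and stromal, endothelial and muscle markers (0.625). In these lists DESeq2 called Tnfrsf4 among the receptors, Ccnb2 and Tyms in the cell cycle list, Cd44 in the homing list and Hif1a in the glycolysis list, all higher.

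Too few members of 5 lists were tested for camera: 3 of the eosinophil, basophil and mast cell markers, 1 neutrophil marker, 2 enteric glia and neuron markers, 0 erythroid genes and 4 sex-linked genes. Adjusted over the list alone, the mast cell protease gene Cpa3 fell from 1.16 ± 0.23 CPM to 0 counts, at least 19.6-fold, and Uchl1 rose from 0.071 ± 0.10 to 1.39 ± 0.11 CPM. Over all genes 0 members of these lists passed by edgeR, and DESeq2 called 0. By fry, which asks whether a list's genes share a direction without comparing them with other genes, 0 of 28 lists passed. Its test for change in either direction passed 8 lists. By its adjusted p, these were the sensing and ILC3 lists (both 0.00381) and the inhibitory (0.00910), homing (0.0109) and receptor (0.0218) lists. The ILC2 identity, immediate early and endoplasmic reticulum stress lists, each at 0.0362, completed the 8.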

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

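With 2 mice per diet, the count of genes depended on the fit, the filter and the libraries kept. The 4 higher genes kept their calls with RLE (5 genes higher), upper-quartile (6) or no (5) scaling factors, without ribosomal, mitochondrial and hemoglobin genes (4) and with DESeq2, and the stricter filter gave 8 higher and 1 lower, Egr1. Robust fitting called 3. There were 0 higher genes without a filter on low counts, with limma-voom or with edgeR's legacy fit, and the cause was not tested. Without the filter 15425 genes were tested, yet fewer reached an unadjusted p under 0.05 than the main fit's 557 higher and 485 lower. All 3 fits also gave 0 lower genes, and unadjusted p under 0.05 was reached by 502 higher and 423 lower genes without the filter, by 443 and 370 with limma-voom and by 461 and 377 with the legacy fit. Adjusted p of Ctla4 ranged from 1.91e-35 with DESeq2 to 0.612 with limma-voom among the planned fits. At an adjusted p of 0.1 the count was 6. Without 1 library edgeR called 0 to 1 genes higher, with fewer samples; the 1 was Igkv14-111, without high-fiber library 1. DESeq2 called 158 genes higher and 78 lower. In fits added after seeing the data it called 157 and 76 on the genes kept by filterByExpr, and without 1 library 98 to 223 higher and 11 to 553 lower, keeping the 4 genes each time. A group left with 1 library was assumed to vary like the other.

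The libraries share only their numbers 1 and 2 between diets, each from its own mouse. Deviations of library 1 from library 2 correlated at 0.041 across genes between the diets. With the replicate block, edgeR called 0 genes higher and 0 lower leaving 1 residual degree of freedom, at unadjusted p under 0.05 for 564 higher and 510 lower genes. DESeq2 with the replicate block, added after seeing the data, called 172 higher and 83 lower. The log2 fold change of Il17rb was -0.0028 with the replicate block.

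Lists called higher numbered 7 and lists called lower 3. With RLE they numbered 5 and 2, with upper-quartile scaling 6 and 2 and with limma-voom 5 and 2. Without 1 library 4 to 6 were higher and 2 to 4 lower; with an estimated correlation or with fry there were 0 higher and 0 lower. The ILC3 list turned to lower with limma-voom (signed adjusted p = -0.772), and the heat shock list to higher without control library 2 (0.342); these causes were not tested.

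Among the 10 genes of smallest p in each direction no sign turned without 1 library. The groups of these genes did not overlap, so leaving out 1 library could hardly turn a sign. Their kept signs are therefore no test of the genes. The widest log2 ranges were -11.54 to -4.52 for Ahrr, 9.80 to 14.48 for Ctla4, -7.26 to -3.93 for Camsap2, 3.73 to 5.93 for Penk and 4.42 to 5.79 for Il17f. Outside these genes, Apoe ranged from 0.36 to 1.23 and Lyz2 from 0.24 to 2.02.

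Other reversals lay in genes that did not pass. Without scaling factors Rora was at -0.022 and Il17rb at -0.044, and with limma-voom Il17rb was at -0.0043. Over the edgeR and DESeq2 fits without 1 library, log2 fold changes ranged from -0.76 to 0.023 for Gata3, from -0.37 to 0.015 for Klrg1, from -0.29 to 0.41 for Rora, from -0.36 to 0.55 for Il13, from -0.11 to 0.34 for Areg and from -0.13 to 0.15 for Il17rb. They ranged from -2.74 to 5.92 for Mki67, from -0.52 to 0.12 for Ddx3y, from -0.033 to 0.22 for Eif2s3y, from -0.20 to 0.12 for Tmem176b and from -0.40 to 0.031 for Ighm. The cause was not tested. The signed adjusted p of the heat shock list ranged from -0.371 to 0.342 over the same edgeR fits, and it passed without control library 1 (-1.74e-11) and without high-fiber library 2 (-0.0485). Scaling alternatives moved the median of all genes by at most 0.040 on the log2 scale (-0.040 without factors).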

Other observations

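The single genes in this and the next paragraph were chosen after their values were seen. None passed with edgeR, all were called by DESeq2, and they were not tested as a list. DESeq2 also called a mean of 46.8 genes in simulations with no changed gene, so its calls here may include false ones. Tph1, the enzyme that starts peripheral serotonin synthesis, was at 45.1 ± 43.3 CPM on the control and 788 ± 267 CPM on the high-fiber diet (log2 fold change 4.08 ± 0.67, edgeR adjusted p = 0.336, DESeq2 adjusted p = 2.00e-09). Calca, which encodes calcitonin gene-related peptide, was at 937 ± 394 and 2299 ± 601 CPM (1.29 ± 0.35, edgeR adjusted p = 0.447, DESeq2 0.0121). Grp, which encodes gastrin-releasing peptide, was at 1.09 ± 1.13 and 31.5 ± 3.21 CPM (4.68 ± 0.70, edgeR adjusted p = 0.256, DESeq2 2.47e-06). Npy, which encodes neuropeptide Y, had 0 counts on the control diet and 357 and 47 counts in high-fiber libraries 1 and 2. Pooled over these libraries, Npy was at least 140.0-fold higher against 3 counts over the group (edgeR adjusted p = 0.447, DESeq2 2.05e-04). Cpe, a carboxypeptidase that trims peptide hormones, had 245 and 73 counts on the control and 0 on the high-fiber diet, at least 102-fold lower (edgeR adjusted p = 0.447, DESeq2 4.23e-04). In control library 2 Tph1, Grp and Penk stood lower than in control library 1, at 14.4, 0.29 and 4.34 CPM against 75.7, 1.89 and 19.8 CPM.

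Ccn2, a matricellular protein gene, had 0 counts on the control and 603 and 448 on the high-fiber diet, at least 364-fold higher (edgeR adjusted p = 0.358, DESeq2 7.28e-10). Mmp12, a macrophage elastase gene, had 0 counts on the control and 652 and 279 on the high-fiber diet, at least 323-fold higher (edgeR adjusted p = 0.427, DESeq2 6.29e-09). Cd52, a lymphocyte surface glycoprotein gene, was at 564 ± 81.3 and 1676 ± 85 CPM (1.57 ± 0.22, edgeR adjusted p = 0.239, DESeq2 1.89e-09). Of the 236 genes DESeq2 called, 58 had 0 counts in one diet.

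The tests of marker gains, of library order, of kappa V genes and of the heat shock median below were chosen only after the results were seen, and so were their limits, as were the splits of the libraries; edgeR, DESeq2, camera and fry were set before, except edgeR's legacy setting, on which the 4 calls rest. Ctla4, Il17a and Tnfsf8 were called higher on the high-fiber diet, with Il17f above the threshold (adjusted p = 0.0931), and T cells or ILC3s in the sorted cells are candidate sources. Among the 12 T cell markers under 20 CPM in both control libraries, the largest gain was 2.09 CPM (Foxp3), against 122 CPM for Ctla4. This argues against T cells as the source of Ctla4, although Cd8a, Cd8b1 and Cd5 were at 0 CPM in both diets. The test also left out markers too abundant on the control diet, such as Cd3g, which went from 157 to 267 CPM. Among the ILC3 markers under 20 CPM in both control libraries, 6 genes without Il17a and Il17f, the largest gain was 0.32 CPM, for Cxcr5, against 84.5 CPM for Il17a, which argues against ILC3s as its source, although 3 of the 6 had 0 counts in all 4 libraries. Of the 3 splits of the 4 libraries into pairs, 1, the real one, gave 4 genes and the highest other 0, too few splits for a share under 0.05. DESeq2 called 236 genes with the real split against 53 and 38. The other splits put both diets in each group, so a diet difference would itself widen the spread within groups. These counts therefore cannot decide whether the calls arose by chance. A diet effect on ILC2s, or on which of them the gate took, is a hypothesis that stays open, as does a difference between these mice apart from diet.

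The B and plasma cell list ranked higher on the high-fiber diet by camera at the preset correlation only (adjusted p = 0.776 with an estimated one), with 0 of 8 members passing over all genes by edgeR and 0 by DESeq2. Outside the list, DESeq2 called the V genes Ighv2-6 (DESeq2 adjusted p = 7.66e-14), Igkv3-10 (2.27e-04) and Igkv14-111 (3.50e-04) higher. Ighv2-6 and Igkv3-10 had counts only in high-fiber library 1, at 17.5 and 25.6 CPM. Plasma cells or their RNA in the sorts may be the source of what difference there is. Igha and Jchain put the 4 libraries in the order of Igkc, which a shared source needs, but these genes were picked after their values were seen. Ighm, the most abundant member, had another order. It was at 482 and 615 CPM in control libraries 1 and 2 and at 418 and 548 CPM in high-fiber libraries 1 and 2. Kappa V transcripts were led by a different gene in each library: Igkv14-111 with 98.6% of kappa V counts in high-fiber library 2, Igkv8-30 with 55.9% in high-fiber library 1, Igkv10-94 with 61.9% in control library 1 and Igkv1-117 with 35.6% of 45 counts in control library 2. This would follow from few cells or clones per library, and whether the number of such cells follows the diet or the sort of each mouse stays open.

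The immediate early list ranked lower on the high-fiber diet by camera at the preset correlation, but not with an estimated one (adjusted p = 0.776) or with fry (0.338), and 0 of 35 members passed over all genes by edgeR. A difference in handling of the cells is a candidate explanation beside an effect of the diet on stimulation. Handling stress that also induces heat shock genes would lower both lists whichever control library is used. Without control library 2 the median of the heat shock genes was 0.245 with a standard error of 0.50 over 16 members, 11 of them positive, while that of the immediate early genes was -0.57. The spread of the heat shock genes is too wide for this to decide, and the labels give no time or order of the sorts, so handling and diet cannot be told apart for the immediate early genes.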
